A study of Mus musculus with 22 samples.

How the data were processed

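RNA was sequenced from mouse placenta at embryonic day 11.5 and 13.5 and from the labyrinth, the exchange layer of the placenta, at day 18.5. The 22 libraries were made from polyadenylated RNA with Illumina kits after extraction on RNeasy columns. They form 10 groups. At E11.5, WT and Mbnl3 knockout (KO) placentas had 3 libraries each, and the litter codes EG, MG and PG occur once in each group. At E13.5 and at E18.5 there were 4 genotypes with 2 libraries each: WT, Mbnl3 KO, Mbnl2 KO and the Mbnl2/Mbnl3 double knockout (DKO). Per the labels, the libraries EG and MG hold placentas of 1 litter each and those coded PG of 2 litters. The labels of the later libraries do not say how many animals each one holds, so p-values here measure the spread between these samples only. Stage and tissue change together between E13.5 and E18.5, and no day, lane or sex is given.

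The authors deposited 2 values per gene and library: read counts without normalization, and cRPKM, which are RPKM (reads per kilobase, scaled to the mapped reads) with a gene length corrected by the authors. The genome build was mm10 in the submitters' processing notes, and the aligner, the counting program and the corrected lengths are not given in the sources used here. Within each library the ratio of count to cRPKM of a gene was checked over 2449 genes at a cRPKM of 20 or more; its relative SD over libraries, after scaling, was at most 0.018%. Of 36902 genes listed, 3342 (9.1%) had no value in any library and were left out, and 33560 had counts. Gene symbols, positions and biotypes came from GENCODE M21, which held 33371 of these identifiers. Reads shared between paralogs are divided in an unknown way, so single members of the prolactin, cathepsin, pregnancy-specific glycoprotein, Ceacam, Serpinb9, granzyme and ribosomal protein families are less certain than their groups. Whether counts separate the strands is not given, and antisense genes are read with the same caution. Total counts per library ranged from 21941855 to 50822896. Between replicates, the spread of counts was larger than counting error, with a chi-squared per degree of freedom of 9.6 to 243.6 over genes with a summed count of at least 20.

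Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group, estimateDisp, glmQLFit with robust set, and glmQLFTest, two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of its fit. There was 1 fit per stage, with 14795 genes and 6 libraries at E11.5, 15551 genes and 8 libraries at E13.5, and 15055 genes and 8 libraries at E18.5. Groups of 2 libraries thereby share the spread estimated over all 4 genotypes of their stage. The knockout effects of Mbnl3 KO and of DKO were compared between stages in 1 fit of 16007 genes over 16 libraries, as the difference of the differences. Levels are CPM, counts divided by the TMM-scaled library size in the usual unit of the cpm function, given as the mean ± SD of a group. Log2 changes are given ± SE, where SE is the size of the log2 change divided by the square root of F. Another scaling, by DESeq2 size factors or by total counts, moved the median log2 change of all genes by at most 0.047.

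Gene lists were written before the data were examined: 37 lists with 586 entries and 580 distinct genes, of which 566 had counts. They cover trophoblast, endothelial, mesenchymal, blood, decidual, natural killer and yolk sac cell types, transport, growth and stress programmes, and the genes flanking Mbnl2 and Mbnl3. Each list with at least 3 tested members was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between members of 0.01, and p was adjusted over the lists of a comparison. camera compares the members of a list with all other genes. The same test with a correlation estimated from the libraries is given beside it. Median, mean and test had the same sign in every list called. For each list, calls were counted at the p adjusted over all genes and adjusted over the list alone. The list tests of DKO against Mbnl3 KO were added after the other comparisons had been fixed.

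The comparisons, tests, lists and the rule for naming genes were chosen before the data were examined. Genes named by the rule were, per direction, the 12 called genes with the largest log2 change in a comparison with WT, and 5 for DKO against Mbnl3 KO, with a mean of at least 1 CPM in 1 group and every knockout library on the same side of all reference libraries; where no gene passed in a direction, the 5 with the smallest p were taken. Predicted genes without a proper name count among the calls but are not named. Within the lists described, up to 4 members with the smallest p were named, and Mbnl1, Mbnl2 and Mbnl3 in every comparison. Fold changes of genes at a mean below 1 CPM in a group rest on few reads.

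The same steps were tested on simulated data, drawn from negative binomial distributions with the means, library sizes and dispersions of these libraries, with 200 genes changed. At E11.5, 19.4% of genes changed by 1.5-fold, 60% of those changed by 2-fold and 92.1% of those changed by 4-fold were called. For DKO these shares were 49.3%, 78.8% and 93.9% at E13.5, and 40.9%, 83.6% and 87.5% at E18.5. For the stage difference of DKO they were 19.4%, 61.2% and 78.8%. Unchanged genes made up 7 of 121, 10 of 167, 13 of 155 and 5 of 117 calls, and 0 genes were called in the wrong direction. A list of 15 members raised 1.5-fold reached a camera adjusted p of 1.1e-13, 9.3e-32 and 5.6e-13 at the 3 stages with the preset correlation. With the estimated one it reached 0.11, 0.039 and 0.038. Each stage had 31 lists, the raised one included, and 0 unchanged lists were called. Genes were drawn independently, so this cannot judge either test on co-expressed lists.

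Alternatives were each set against the edgeR test: DESeq2 size factors (RLE) in edgeR, no filter on low counts beyond 1 read, the Wald test of DESeq2 1.42.0, limma with a trend on log2(cRPKM + 0.5) for genes at a cRPKM of 1 or more, a replicate block, each library left out in turn, the estimated correlation for lists, and overlaps at an adjusted p below 0.1. DESeq2 and limma also test other sets of genes (13164 to 15006 and 12054 in comparisons at E13.5), and limma other values, so their counts do not move by the test alone. With 1 library left in a group, that library is assumed to vary like those of the other groups. At E11.5 the libraries of a litter resembled each other across genotypes after removal of the group means, with correlations across genes of 0.61 (EG), 0.7 (MG) and 0.24 (PG) against at most -0.16, -0.04 and 0.15 with another litter, so the block pairs libraries by code there, with little support for PG. After the data had been seen, mean log2 CPM of the Y-linked genes, the yolk sac list and the natural killer list were added as covariates, 1 at a time, in the counts at E13.5 and E18.5. Where 2 comparisons share the WT libraries, the overlap of their calls was set beside the product of both counts over the genes tested and the mean of 20 simulations of groups without effects that share the controls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.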

Results

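Mbnl1, Mbnl2 and Mbnl3 encode muscleblind-like proteins, which bind RNA and regulate its splicing and fate. Transcript levels were measured by RNA sequencing in 22 libraries of mouse placenta that differ in Mbnl2 and Mbnl3 genotype. At E11.5 there were 3 Mbnl3 KO and 3 WT placenta libraries, paired by litter code. At E13.5 the placenta and at E18.5 the labyrinth were sampled in WT, Mbnl3 KO, Mbnl2 KO and DKO, with 2 libraries per genotype and stage. Total counts per library were 29052657 to 50822896 at E11.5, 37687617 to 49771099 at E13.5 and 21941855 to 30772753 at E18.5. The first principal component separated litters at E11.5 (58.6% of the variance) and set both DKO libraries apart from the other 6 at E13.5 (25.5%) and at E18.5 (37.2%). At E11.5, WT library MG had 3.95% of its counts in Gm42418, at 40600 CPM against 1060 to 1790 CPM in the other 5. Levels below are mean CPM ± SD over the libraries of a group. Changes are log2 ± SE, and calls rest on the edgeR test.

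Mbnl3 lies on chromosome X at 51117269 to 51206532 (minus strand, ENSMUSG00000036109, mm10). Mbnl2 lies on chromosome 14 at 120275669 to 120431697 (plus strand, ENSMUSG00000022139) and Mbnl1 on chromosome 3 at 60472830 to 60629750 (plus strand, ENSMUSG00000027763). Mbnl3 was at 182.7 ± 12.8 CPM in WT at E11.5 (n = 3), 163.8 ± 4.31 at E13.5 and 160.8 ± 17.8 at E18.5 (n = 2 each). In Mbnl3 KO it was at 1.67 ± 0.0777, 1.494 ± 0.444 and 1.951 ± 0.392 CPM. The changes were -6.77 ± 0.13 (adjusted p = 1.3e-06), -6.76 ± 0.12 (adjusted p = 2e-11) and -6.36 ± 0.15 (adjusted p = 2.5e-10). In DKO it was at 1.038 ± 0.0286 CPM at E13.5 (-7.3 ± 0.13, adjusted p = 1.6e-11) and 1.235 ± 0.0331 at E18.5 (-7.02 ± 0.15, adjusted p = 1.2e-10). DKO differed from Mbnl3 KO by -0.54 ± 0.19 (adjusted p = 0.21) and -0.66 ± 0.21 (adjusted p = 0.069). In the libraries labelled Mbnl2 KO, Mbnl3 stayed at 176 ± 0.272 CPM at E13.5 (0.1 ± 0.08, adjusted p = 0.77) and 142.4 ± 7.25 at E18.5 (-0.18 ± 0.1, adjusted p = 0.54).

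Mbnl2 was not lower in any group labelled as lacking it. It was at 292.5 ± 20 CPM in WT and 289.3 ± 24 in the libraries labelled Mbnl2 KO at E13.5 (-0.02 ± 0.08, adjusted p = 0.98). At E18.5 it was at 266.2 ± 34.2 and 298.4 ± 27.2 CPM (0.16 ± 0.12, adjusted p = 0.66). In DKO it was at 308.2 ± 31.5 CPM at E13.5 (0.08 ± 0.08, adjusted p = 0.66) and 327.2 ± 49.3 at E18.5 (0.3 ± 0.12, adjusted p = 0.13). Against Mbnl3 KO the changes were 0.13 ± 0.08 (adjusted p = 0.48) and 0.18 ± 0.12 (adjusted p = 0.42). Mbnl3 KO had 207.1 ± 21.6 CPM at E11.5, where WT had 221.6 ± 17.9 (-0.1 ± 0.12, adjusted p = 1). It had 280.8 ± 7.05 at E13.5 and 289.8 ± 1.91 at E18.5 (adjusted p = 0.87 and 0.89). At E13.5 the sign of these small changes turned when WT replicate 1 (Mbnl3 KO, to 0.02, and libraries labelled Mbnl2 KO, to 0.06), replicate 1 of the libraries labelled Mbnl2 KO (to 0.07) or DKO replicate 2 (to -0.03) was left out. The gene count did not tell the Mbnl2 genotypes apart. Every statement on Mbnl2 KO or DKO follows the labels. Mbnl1 did not pass the test in any comparison. It was at 37.06 ± 2.42 CPM in WT and 33.42 ± 5.73 in Mbnl3 KO at E11.5 (-0.15 ± 0.14). Group means were 24.47 ± 2.27 to 30.67 ± 0.308 CPM at E13.5 and 31.96 ± 0.981 to 39.55 ± 1.84 CPM at E18.5.

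**Figure D1:**
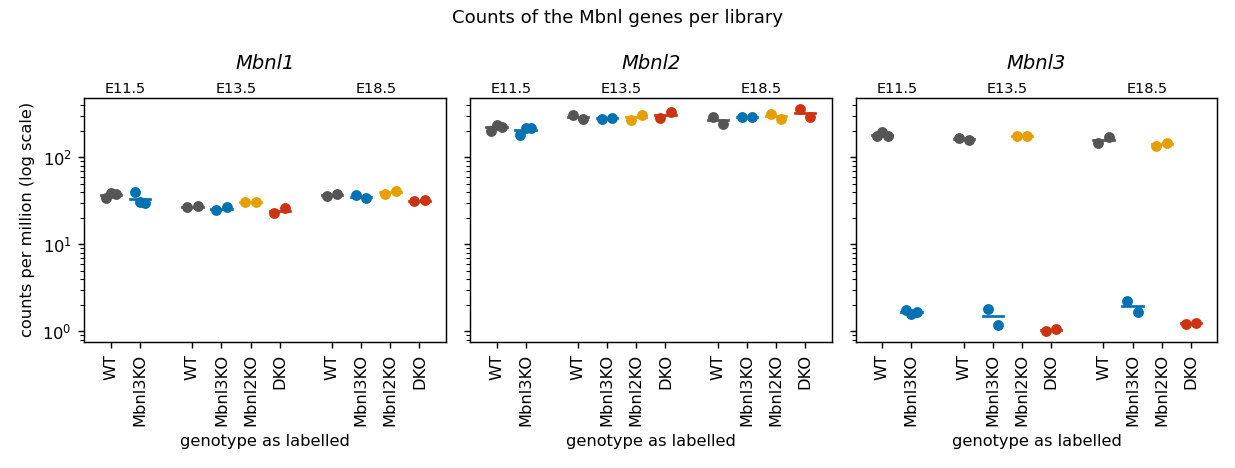
CPM (log axis) of Mbnl1, Mbnl2 and Mbnl3 in each library (dots) with group means (bars). Mbnl3 lies between 1.038 and 1.951 CPM on average in Mbnl3 KO and DKO and at 142.4 CPM or more in the other groups, while Mbnl2 lies between 207.1 and 327.2 CPM in all 10 groups.

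At E11.5, Mbnl3 KO against WT asked what Mbnl3 loss does in the early placenta. Mbnl3 was the only gene called among 14795 tested. As groups, markers of the trophoblast that borders maternal blood and of the junctional zone lay lower in Mbnl3 KO, and markers of the outer syncytial layer lay higher. These calls ended with an estimated correlation and without WT library EG, whose loss unbalances litters, but held with the litter block. With edgeR, litters unpaired, 289 genes had an unadjusted p under 0.05 against 740 expected by chance. DESeq2 called 2, limma 1, edgeR with the block 1 (1353 at an unadjusted p under 0.05), and any library left out 1. The 5 higher genes with the smallest p were Cnih2, Crtac1, Ckmt1, Syt13 and Ckb, none called (adjusted p = 1, 0.2 to 0.23 with the block).

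At E11.5, 11 of 37 lists were called, 3 higher and 8 lower, and 0 with an estimated correlation (1 list at an unadjusted p under 0.05). The pregnancy-specific glycoproteins, secreted by spongiotrophoblast and giant cells, had 17 of 18 members below 0 (median -0.74, adjusted p = 1.41e-06, adjusted p = 0.647 with an estimated correlation). Placental cathepsins and sinusoidal giant cell markers lay lower (median -0.54, adjusted p = 1.95e-06), with 0 members called over all genes and 2 adjusted over the list alone. These were Lepr, the leptin receptor, at 37.23 ± 1.62 against 55.22 ± 3.7 CPM (-0.57 ± 0.1), and Ctsq at 226.8 ± 14.5 against 339.9 ± 66.1 CPM (-0.58 ± 0.15). Spongiotrophoblast markers also lay lower (median -0.52, adjusted p = 0.00454). Markers of syncytiotrophoblast layer I lay higher (median 0.13, adjusted p = 0.000679). The other lists called (adjusted p = 0.00183 to 0.0481) had medians of 0.07 (cell cycle), 0.09 (glycogen cells), -0.07 (fetal endothelium), -0.12 (interferon response), -0.16 (mesenchyme), -0.18 (macrophages) and -0.19 (definitive erythroid genes, 11 of 11 below 0). With an estimated correlation these 11 lists had an adjusted p of 0.647 to 0.73. Without WT library EG the cathepsin (adjusted p = 0.094), glycoprotein (adjusted p = 0.094), spongiotrophoblast (adjusted p = 0.65) and syncytiotrophoblast layer I calls (adjusted p = 0.46) ended. Without that library or Mbnl3 KO library MG, 3 of the 11 lists kept their call each time, and each list lost it without 1 or more of the 6 libraries (adjusted p to 0.97). With the litter block 15 lists were called, adding extracellular matrix (adjusted p = 0.029), glycolysis (0.0411), unfolded protein response (0.0452) and primitive globins (0.0459).

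At E13.5 the same question was asked with 2 libraries per group. A few single genes rose, among them the lipase gene Lipg. As groups, nutrient transport and outer syncytial genes lay higher and sinusoidal giant cell genes lower, but none held with an estimated correlation, nor the first 2 without WT replicate 1. The edgeR test called 14 genes (11 higher, 3 lower), with 1493 genes at an unadjusted p under 0.05 against 778 expected by chance. Lipg, endothelial lipase, rose from 179.8 ± 1.98 to 321.5 ± 15.2 CPM (0.84 ± 0.07, adjusted p = 0.00048). The protease inhibitor Wfdc2 rose from 81.48 ± 9.59 to 156.5 ± 7.36 CPM (0.94 ± 0.11, adjusted p = 0.018). The vesicle GTPase gene Rab3b rose from 5.077 ± 0.12 to 9.106 ± 0.373 (0.84 ± 0.11, adjusted p = 0.018) and BC053393 from 2.712 ± 0.446 to 7.833 ± 1.23 (1.54 ± 0.19, adjusted p = 0.015). Hadh, of mitochondrial fatty acid oxidation, rose from 175.7 ± 6.3 to 240.8 ± 19 CPM (0.45 ± 0.07, adjusted p = 0.031). Anxa5, an annexin that binds phosphatidylserine, rose from 473 ± 1.33 to 614.7 ± 29 (0.38 ± 0.06, adjusted p = 0.031). Cacng5, Colq, Tmprss2, Sept4 and Atp6ap1 rose by 0.38 or more, and Mir6240 fell by 0.96 with Mbnl3. Leaving out 1 library left 2 calls (Mbnl3 KO replicate 1), 5 (Mbnl3 KO replicate 2), 3 (WT replicate 1) or 6 (WT replicate 2). Of the named genes Mbnl3 and Lipg were called each time. Each of the others lost its call without at least 1 of these 4 libraries, with the adjusted p reaching 0.36. The count was 85 with DESeq2, 339 without the filter and 3 with limma, where the higher share went from 78.6% to 33.3%. With indices chosen after the data were seen it was 2 (Y-linked) and 50 (natural killer).

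In Mbnl3 KO at E13.5, 5 of 37 lists were called (3 higher, 2 lower), and 0 with an estimated correlation (2 at an unadjusted p under 0.05). Amino acid, glucose, lipid and iron transport lay higher (median 0.1, adjusted p = 0.00227, adjusted p = 0.718 with an estimated correlation), with 1 member called and 4 adjusted over the list alone. Syncytiotrophoblast layer I markers lay higher (median 0.15, adjusted p = 0.0043, adjusted p = 0.718 with an estimated correlation), with 0 members called and 2 adjusted over the list alone. The cathepsin and sinusoidal giant cell list lay lower (median -0.32, adjusted p = 0.00018, adjusted p = 0.378 with an estimated correlation), with 0 called and 4 adjusted over the list alone. Ctsq was at 957.4 ± 71.7 against 1324 ± 17.9 CPM (-0.47 ± 0.08, adjusted p = 0.059). Immediate early genes lay lower (median -0.15, adjusted p = 0.0043) and the genes flanking Mbnl3 on chromosome X higher (median 0.19, adjusted p = 0.0165; 0 called, 1 adjusted over the list alone). Without WT replicate 1 the transport (adjusted p = 0.085), syncytial (adjusted p = 0.053) and flanking gene calls (adjusted p = 0.2) ended, the last also without Mbnl3 KO replicate 1 (adjusted p = 0.1).

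Loss of Mbnl2 alone, as labelled, was asked about at E13.5 next. Single genes barely passed the test, whereas markers of vessels, mesenchyme and blood lay higher as groups, together with markers of yolk sac endoderm. None of these held with an estimated correlation, nor the vessel markers without WT replicate 1 and the blood markers without replicate 1 of these libraries. In the libraries labelled Mbnl2 KO, Cyp46a1, the cholesterol 24-hydroxylase gene (chromosome 12, 108334381 to 108362234), rose from 1.307 ± 0.271 to 3.54 ± 0.309 CPM (1.43 ± 0.18, adjusted p = 0.03). The membrane-traffic GTPase gene Rab12 fell from 62.65 ± 0.74 to 44.25 ± 0.242 CPM (-0.5 ± 0.06, adjusted p = 0.03). These 2 were the only edgeR calls, with 1359 genes at an unadjusted p under 0.05 against 778 expected by chance. DESeq2 called 34, limma 1 and edgeR without the filter 327. Leaving out any of the 4 libraries ended both calls. edgeR then called 0 genes, with 722 (replicate 1 of the libraries labelled Mbnl2 KO), 1201 (their replicate 2), 954 (WT replicate 1) and 1208 genes (WT replicate 2) at an unadjusted p under 0.05. The adjusted p reached 0.34 for Cyp46a1 and 0.79 for Rab12.

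In these libraries at E13.5, 13 of 37 lists were called (10 higher, 3 lower), 0 with an estimated correlation (2 at an unadjusted p under 0.05). Yolk sac endoderm markers lay highest (median 1.07, adjusted p = 2.02e-07; 0 called, 3 adjusted over the list alone). Their mean log2 CPM was 3.28 and 2.71 (WT 2.14 and 2.23), but differed widely within Mbnl3 KO (1.73 and 2.95). Fetal endothelial markers lay higher (median 0.14, adjusted p = 3.51e-05; 0 called, 2 adjusted over the list alone). This call ended without WT replicate 1. Medians were also above 0 (adjusted p = 0.000206 to 0.0338) in definitive erythroid genes (0.31), mesenchyme (0.27), macrophages (0.23), cell cycle (0.1), extracellular matrix (0.09), syncytiotrophoblast layer I (0.09), transport (0.06) and ribosomal proteins (0.06). They were lower in the cathepsin and sinusoidal list (-0.23, adjusted p = 1.31e-06; 0 called, 5 adjusted over the list alone). So they were in nuclear long noncoding RNAs (-0.46, adjusted p = 0.000218; 0 called, 4 adjusted over the list alone) and in immediate early genes (-0.15, adjusted p = 0.00157). With an estimated correlation the adjusted p of these 13 lists was 0.36 to 0.725. The yolk sac, mesenchyme, macrophage, cathepsin, noncoding RNA and immediate early calls held whichever library was left out. The others ended without WT replicate 1, WT replicate 2 or replicate 1 of the libraries labelled Mbnl2 KO (adjusted p to 0.74).

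The DKO libraries of the E13.5 placenta differed from WT in more genes. Some genes of basement membrane (Lamc1), imprinted growth control (Igf2) and trophoblast progenitors (Esrrb) rose in the DKO libraries, while Ctsq and Lepr of sinusoidal giant cells and some placental prolactins fell. None of their lists was called with an estimated correlation. The edgeR test called 595 genes (409 higher, 186 lower; 61 changed at least 2-fold), with 3084 at an unadjusted p under 0.05 against 778 expected by chance. Cyp46a1 rose from 1.307 ± 0.271 to 8.417 ± 0.0404 CPM (2.68 ± 0.17, adjusted p = 1.1e-05). The adhesion genes Ceacam2 and Ceacam1 rose from 21.62 ± 2.51 to 55.58 ± 3.27 CPM (1.36 ± 0.09, adjusted p = 1.1e-05) and from 9.768 ± 1.92 to 24.35 ± 1.23 CPM (1.32 ± 0.12, adjusted p = 0.00021). The ligand gene Bmp10 rose from 0.8494 ± 0.0371 to 2.456 ± 0.283 CPM (1.53 ± 0.21, adjusted p = 0.0033). Igfbp1, for a carrier of insulin-like growth factors, rose from 1.16 ± 0.477 to 4.686 ± 1.96 (1.99 ± 0.41, adjusted p = 0.037). Gpr137c, BC053393, Clec2l, Ighg1, Mlana, Crtac1 and Tmem266 rose by 1.44 to 2.05. Bcl6, for a transcriptional repressor, fell from 15.06 ± 0.705 to 4.429 ± 0.441 CPM (-1.77 ± 0.11, adjusted p = 1.1e-05). Fndc5, for the precursor of irisin, fell from 9.903 ± 0.415 to 2.24 ± 0.369 (-2.14 ± 0.18, adjusted p = 7e-05) and Prl3c1 from 27.34 ± 0.765 to 8.887 ± 3.05 (-1.62 ± 0.21, adjusted p = 0.0093). Trarg1, Spata20, Nr4a3, Slc9b2 and Ttyh1 fell, with changes of -1.75, -1.57, -1.25, -1.23 and -1.19. Of the named genes, Cyp46a1, BC053393, Bmp10, Ceacam1, Ceacam2, Tmem266, Bcl6, Fndc5, Nr4a3, Mbnl3, Cts6, Lepr, Ctsq, Ctsj and Ddx3y were called whichever library was left out. The rest lost their call without WT replicate 1, WT replicate 2, DKO replicate 1 or DKO replicate 2, with the adjusted p reaching 0.25.

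The E13.5 DKO count was 519 without DKO replicate 1, 397 without DKO replicate 2, 206 without WT replicate 1 and 103 without WT replicate 2. Sex-linked and other cell-type markers moved with the groups here. The Y-linked genes were lower in DKO (median -0.56, adjusted p = 5.35e-05, adjusted p = 0.177 with an estimated correlation; 3 called, 4 adjusted over the list alone). Ddx3y fell from 38.05 ± 0.825 to 27.33 ± 0.699 CPM (-0.48 ± 0.07, adjusted p = 0.0039). The others were Kdm5d (-0.63 ± 0.13, adjusted p = 0.021), Uty (-0.49 ± 0.11, adjusted p = 0.028) and Eif2s3y (-1.06 ± 0.31, adjusted p = 0.12). Uty lost its call without any 1 of the 4 libraries (adjusted p to 0.14) and Kdm5d without DKO replicate 1, DKO replicate 2 or WT replicate 2 (to 0.16). Xist, from the inactive X chromosome, did not pass (-0.49 ± 0.38). Natural killer cell markers of the uterus were also lower (median -1.24, adjusted p = 0.000158, adjusted p = 0.747 with an estimated correlation, 0 called). With the Y-linked index of each library as a covariate, chosen after the data were seen, 1 gene was called, against 525 with the yolk sac index and 259 with the natural killer index. limma called 209 genes, and DESeq2 838.

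In DKO at E13.5, 11 of 37 lists were called (7 higher, 4 lower), 0 with an estimated correlation (4 at an unadjusted p under 0.05). Extracellular matrix genes had all 20 members above 0 (median 0.2, adjusted p = 1.06e-06, adjusted p = 0.418 with an estimated correlation), with 5 called and 8 adjusted over the list alone. The basement membrane genes Lamc1 (855.1 ± 16.2 to 1105 ± 17.7 CPM, 0.37 ± 0.07, adjusted p = 0.012), Lamb1 (0.38 ± 0.07, adjusted p = 0.013) rose. So did Col4a2 (1344 ± 99.4 to 1803 ± 25.8 CPM, 0.42 ± 0.09, adjusted p = 0.022) and the collagen crosslinker gene Loxl2 (0.32 ± 0.06, adjusted p = 0.016). Imprinted genes lay higher (median 0.11, adjusted p = 0.0136, adjusted p = 0.481 with an estimated correlation; 3 called, 6 adjusted over the list alone). Igf2 rose from 2997 ± 21.8 to 3752 ± 6.48 CPM (0.32 ± 0.06, adjusted p = 0.01), Sgce by 0.37 and H19 from 9626 ± 531 to 11680 ± 755 CPM (0.28 ± 0.07, adjusted p = 0.044). Trophoblast progenitor markers lay higher (median 0.2, adjusted p = 0.00778, adjusted p = 0.321 with an estimated correlation; 2 called; adjusted over the list alone, 5 higher and 1 lower). Esrrb rose from 7.709 ± 0.702 to 11.25 ± 0.725 CPM (0.55 ± 0.12, adjusted p = 0.029), as did Met (0.49 ± 0.12, adjusted p = 0.044). Glycogen cell genes lay higher (median 0.1, adjusted p = 0.0136, adjusted p = 0.508 with an estimated correlation; 3 called; adjusted over the list alone, 5 higher and 1 lower). Pygl rose from 80.16 ± 1.69 to 106.6 ± 9.45 CPM (0.41 ± 0.08, adjusted p = 0.016). Transport (median 0.11, adjusted p = 0.0168, 3 higher and 1 lower), glycolysis and hypoxia response (median 0.08, adjusted p = 0.0179, 2 higher) and insulin-like growth factor signalling (median 0.11, adjusted p = 0.0417, 2 higher and 1 lower) each had an adjusted p of 0.747 with an estimated correlation. The members named here lost their call without 1 or more of WT replicate 1, WT replicate 2, DKO replicate 1 and DKO replicate 2 (adjusted p to 0.23). Of these 7 list calls, those of extracellular matrix and progenitors held whichever library was left out. The other 5 ended without DKO replicate 2 (adjusted p = 0.055 to 0.66), transport, imprinted genes and growth factor signalling also without WT replicate 1 (to 0.23), and glycolysis without WT replicate 2 (0.1).

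The cathepsin and sinusoidal giant cell list lay lowest among the trophoblast lists called lower in DKO at E13.5 (median -0.54, adjusted p = 1.15e-09, adjusted p = 0.177 with an estimated correlation; 5 of 10 called, 8 adjusted over the list alone). Ctsq fell from 1324 ± 17.9 to 547.1 ± 61.3 CPM (-1.27 ± 0.08, adjusted p = 1.1e-05) and Lepr from 227.5 ± 20.3 to 83.44 ± 9.4 (-1.45 ± 0.09, adjusted p = 1.2e-05). Ctsj fell from 6352 ± 87.4 to 4497 ± 301 (-0.5 ± 0.06, adjusted p = 0.002) and Cts6 from 64.05 ± 10.8 to 6.173 ± 2.63 (-3.38 ± 0.28, adjusted p = 0.005). Spongiotrophoblast markers lay lower (median -0.18, adjusted p = 0.0312, adjusted p = 0.747 with an estimated correlation; 3 lower, list alone 1 higher and 3 lower). Prl8a9 fell from 5750 ± 432 to 4453 ± 410 CPM (-0.37 ± 0.08, adjusted p = 0.028), as did Prl3a1 (-0.91 ± 0.2, adjusted p = 0.028). This list call ended without DKO replicate 1 (adjusted p = 0.17) or WT replicate 1 (0.28). Prl8a9 lost its call without DKO replicate 1, WT replicate 1 or WT replicate 2 (to 0.18) and Prl3a1 without any 1 of the 4 libraries (to 0.12).

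DKO was set against Mbnl3 KO to ask what the labelled loss of Mbnl2 adds where Mbnl3 is absent, in a contrast without the WT libraries, which enter the filter, scaling and spread of the fit alone. At E13.5, Cyp46a1 and the giant cell gene Prl3d3 rose and Ctsq and Lepr of sinusoidal giant cells fell. The edgeR test called 199 genes (147 higher, 52 lower), with 2267 at an unadjusted p under 0.05. Cyp46a1 rose from 1.772 ± 0.0516 CPM (2.25 ± 0.16, adjusted p = 8e-05) and Endou from 0.9878 ± 0.317 to 3.671 ± 1.35 (1.88 ± 0.29, adjusted p = 0.013). Prl3d3, of parietal giant cells, rose from 4.743 ± 0.655 to 10.86 ± 2.67 (1.19 ± 0.19, adjusted p = 0.017), Esyt3 by 1.29 and Pcsk9 by 1.18. Bcl6 fell from 12.08 ± 0.874 CPM (-1.45 ± 0.11, adjusted p = 0.00016) and Cts6 from 29.54 ± 0.587 (-2.26 ± 0.28, adjusted p = 0.031). Fndc5, Gkn2 and Ocm fell with changes of -1.37, -1.33 and -1.23. The cathepsin list was lower (median -0.38, adjusted p = 2.34e-07, adjusted p = 0.206 with an estimated correlation; 4 called, list alone 8 lower and 1 higher). Lepr changed by -1 ± 0.09 (adjusted p = 0.00044), Ctsq by -0.81 ± 0.08 (adjusted p = 5e-04) and Ctsj by -0.47 ± 0.06 (adjusted p = 0.0055). Without Mbnl3 KO replicate 1, 16 genes were called, without DKO replicate 2 129, and without DKO replicate 1 or Mbnl3 KO replicate 2 137 and 193. Cyp46a1, Bcl6, Lepr and Ctsq were called each time. The other genes named here lost theirs without Mbnl3 KO replicate 1, and some also without Mbnl3 KO replicate 2, DKO replicate 1 or DKO replicate 2 (adjusted p to 0.47). There were 32 calls with limma, where the higher share went from 73.9% to 34.4%, 488 with DESeq2 and 84 with the replicate block. With indices chosen after the data were seen, edgeR called 0 with the Y-linked one (530 at an unadjusted p under 0.05), 15 with the natural killer one and 203 with the yolk sac one.

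In this comparison 10 of 37 lists were called (2 higher, 8 lower), 0 with an estimated correlation (3 at an unadjusted p under 0.05). Extracellular matrix genes lay higher (median 0.18, adjusted p = 6.55e-07, adjusted p = 0.533 with an estimated correlation; 3 called, 6 adjusted over the list alone). Loxl2, Lamb1 and Lamc1 passed the threshold (adjusted p = 0.021, 0.032 and 0.043; to 0.39 without Mbnl3 KO replicate 1 and other libraries). The pregnancy-specific glycoproteins lay higher by a median of 0.14 (adjusted p = 0.0462), which turned to -0.07 without DKO replicate 2. Definitive erythroid genes were lower (median -0.4, adjusted p = 0.000428; 0 called, 3 adjusted over the list alone). This call ended without Mbnl3 KO replicate 1 (adjusted p = 0.055). Oxidative phosphorylation (median -0.11), interferon response (-0.18), nuclear long noncoding RNAs (-0.23) and cell cycle (-0.07) were also lower (adjusted p = 0.00238 to 0.0436), with 0 members called. Y-linked genes (median -0.48, adjusted p = 0.000103) and natural killer markers (median -1.41, adjusted p = 1.13e-05) were lower against Mbnl3 KO as against WT. With an estimated correlation, these 10 lists had an adjusted p of 0.206 to 0.761. The extracellular matrix, cathepsin, Y-linked and natural killer calls held whichever library was left out. The others ended without 1 or more of DKO replicate 1, DKO replicate 2, Mbnl3 KO replicate 1 and Mbnl3 KO replicate 2 (adjusted p to 0.85).

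At E18.5 the labyrinth of Mbnl3 KO was compared with WT. With edgeR, almost no single gene passed. Markers of the outer syncytial layer and of the pregnancy-specific glycoprotein family lay higher as groups, and yolk sac markers lay lower. With an estimated correlation only the last held. The glycoprotein call also ended without WT replicate 2 or Mbnl3 KO replicate 2 and the syncytial one without WT replicate 1. Calls were limited to 2 genes: Mbnl3, and Slc39a2, a zinc importer gene that fell from 11.07 ± 1 to 3.7 ± 0.656 CPM (-1.58 ± 0.18, adjusted p = 0.0098). There were 1052 genes at an unadjusted p under 0.05 against 753 expected by chance. DESeq2 called 54, limma 3, edgeR without the filter 131 and with the replicate block 112. Tgfa, for a ligand of the epidermal growth factor receptor, was at 25.86 ± 2.98 against 14.74 ± 1.18 CPM (0.81 ± 0.13, adjusted p = 0.056) and Idh2 at 144.8 ± 5.82 against 96.94 ± 5.99 (0.58 ± 0.09, adjusted p = 0.075). Pstpip1, Slc26a7 and Fxyd4 came next (adjusted p = 0.089 to 0.091). Without WT replicate 1, 36 genes were called (6 higher, 30 lower). Without Mbnl3 KO replicate 1, Mbnl3 KO replicate 2 or WT replicate 2 Slc39a2 lost its call (adjusted p to 0.28), leaving 1.

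In Mbnl3 KO at E18.5, 10 of 36 lists were called (8 higher, 2 lower). The yolk sac endoderm list was the only list called with an estimated correlation in any comparison. Its 13 members were all below 0 (median -0.73, adjusted p = 2.93e-16, adjusted p = 0.0361 with an estimated correlation; 0 called, 10 adjusted over the list alone). Apoa1 was at 49.78 ± 6.61 against 101.7 ± 17.1 CPM (-1.03 ± 0.14, adjusted p = 0.056) and Afp, alpha-fetoprotein, at 354.7 ± 84.3 against 709.2 ± 46.3 CPM (-1 ± 0.16, adjusted p = 0.09). With the yolk sac index as a covariate, chosen after the data were seen, edgeR called 0 genes, with 425 at an unadjusted p under 0.05. This index widened the standard errors 5.2 times in the median, so the lost calls decide nothing. Syncytiotrophoblast layer I markers lay higher (median 0.11, adjusted p = 0.000464, adjusted p = 0.677 with an estimated correlation; 0 called, 3 adjusted over the list alone). The pregnancy-specific glycoproteins lay higher (median 0.37, adjusted p = 0.000237, adjusted p = 0.834 with an estimated correlation), as did (adjusted p = 0.00141 to 0.0463) spongiotrophoblast markers (0.37), macrophages (0.24), cell cycle (0.14), glycolysis (0.09), natural killer markers (0.5) and ribosomal proteins (0.06). Smooth muscle genes lay lower (-0.26, adjusted p = 0.00643; 0 called, 1 adjusted over the list alone). Only the yolk sac call held whichever library was left out. The others ended without 1 or more of Mbnl3 KO replicate 2, WT replicate 1 and WT replicate 2 (adjusted p to 0.92). Leaving out WT replicate 1 turned the ribosomal median to -0.04. Without WT replicate 2 the spongiotrophoblast median was 0.07, with the test on the other side.

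The libraries labelled Mbnl2 KO differed from WT in more genes at E18.5. The steroid and estrogen genes Cyp17a1 and Sult1e1 and 2 parietal giant cell markers rose, and the repressor gene Bcl6, the leptin receptor gene and an interferon regulator fell. With edgeR, calls numbered 138 (87 higher, 51 lower; 34 at least 2-fold), with 1806 at an unadjusted p under 0.05 against 753 expected by chance. Sult1e1, estrogen sulfotransferase, rose from 5.516 ± 0.811 to 16.93 ± 1.12 CPM (1.62 ± 0.14, adjusted p = 0.00024). Esrrb, a nuclear receptor gene of trophoblast progenitors, rose from 4.514 ± 0.214 to 13.02 ± 0.0407 (1.53 ± 0.13, adjusted p = 0.00024). Cyp46a1 rose from 1.133 ± 0.261 to 5.719 ± 0.757 CPM (2.34 ± 0.31, adjusted p = 0.0055) and the potassium channel gene Kcnj5 from 5.756 ± 2.27 to 19.53 ± 0.134 (1.77 ± 0.22, adjusted p = 0.0067). Tmem179, Gsg1l, C2cd4c, Duox1, Ces1a, Tmem266, Sema5b and Tmod1 rose by 1.49 to 2.14. Bcl6 fell from 24.46 ± 2.08 to 7.947 ± 0.198 CPM (-1.62 ± 0.12, adjusted p = 0.00019), the transcription factor gene Taf4b from 19.96 ± 0.4 to 10.32 ± 0.567 (-0.95 ± 0.11, adjusted p = 0.0018). Sbk3, Ccdc42, Abo, Sh3rf3, Uggt2, Gfra3, Cpne8, Tfcp2l1, Fut4 and Ank2 fell, with changes of -3.28, -1.84, -1.65, -1.34, -1.12, -1.03, -0.99, -0.98, -0.93 and -0.92. Leaving out 1 library left 32 calls (replicate 1 of the libraries labelled Mbnl2 KO), 52 (their replicate 2), 188 (WT replicate 1) or 43 (WT replicate 2). Sult1e1, Cyp17a1, Esrrb, Bcl6 and Taf4b were called each time. Cyp46a1 lost its call without WT replicate 2 (adjusted p = 0.064) and Kcnj5 without either replicate labelled Mbnl2 KO (to 0.057). The others lost theirs without 1 to 4 of these libraries (to 0.41). limma called 48 genes, DESeq2 237, edgeR without the filter 446 and with the replicate block 513. The Y-linked and yolk sac indices, chosen after the data were seen, left 79 and 52.

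At E18.5, 10 of 36 lists were called in the libraries labelled Mbnl2 KO (6 higher, 4 lower), 0 with an estimated correlation (1 at an unadjusted p under 0.05). Parietal giant cell markers lay higher (median 0.62, adjusted p = 0.000146, adjusted p = 0.768 with an estimated correlation; 2 of 7 called, 4 adjusted over the list alone). Prl2c5 rose from 145.1 ± 18 to 243.7 ± 22.1 CPM (0.75 ± 0.11, adjusted p = 0.0068) and Serpinb9d from 8.554 ± 0.691 to 13.36 ± 1.03 (0.64 ± 0.13, adjusted p = 0.046). Steroid hormone synthesis lay higher (median 0.19, adjusted p = 0.0281, adjusted p = 0.768 with an estimated correlation; 1 called, 1 adjusted over the list alone). Cyp17a1, for a hydroxylase and lyase of steroids, rose from 86.9 ± 7.99 to 190.4 ± 22.3 CPM (1.13 ± 0.1, adjusted p = 0.00027). Ribosomal protein genes had 28 of 30 members above 0 (median 0.24, adjusted p = 5.49e-09, adjusted p = 0.878 with an estimated correlation; 0 called, 2 adjusted over the list alone). Cholesterol synthesis (median 0.09, adjusted p = 0.0404), mesenchyme (0.14, adjusted p = 0.0281) and nuclear long noncoding RNAs (0.38, adjusted p = 0.0281) also lay higher. Interferon response genes lay lower (median -0.15, adjusted p = 0.000259, adjusted p = 0.768 with an estimated correlation; 1 called, 7 adjusted over the list alone). Stat1 fell from 82.11 ± 8.22 to 57.97 ± 0.657 CPM (-0.5 ± 0.1, adjusted p = 0.033). The cathepsin and sinusoidal list lay lower (median -0.39, adjusted p = 0.0119, adjusted p = 0.878 with an estimated correlation; 1 of 8 called, 3 adjusted over the list alone). Lepr fell from 3841 ± 191 to 2257 ± 6.11 CPM (-0.77 ± 0.13, adjusted p = 0.017). Also lower were transport (median -0.16, adjusted p = 0.0183) and syncytiotrophoblast layer I (-0.19, adjusted p = 0.0404). Only the ribosomal and parietal giant cell calls held whichever library was left out. The steroid, transport, noncoding RNA and syncytial calls ended without WT replicate 2 (adjusted p to 0.91) or replicate 1 of the libraries labelled Mbnl2 KO (to 0.28). The interferon, mesenchyme and cathepsin calls ended without WT replicate 1 (to 0.7), and the cholesterol and cathepsin calls without replicate 2 labelled Mbnl2 KO (to 0.11), the former also without WT replicate 2 (0.16). Cyp17a1 was called each time. Prl2c5 lost its call without replicate 1 of the libraries labelled Mbnl2 KO or WT replicate 2 (to 0.094). Lepr and Stat1 did so without either of those or replicate 2 labelled Mbnl2 KO (to 0.19 and 0.29), and Serpinb9d without any 1 of the 4 (to 0.38).

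The labyrinth of DKO at E18.5 differed most from WT. As groups, genes of cholesterol and steroid hormone synthesis, ribosomal proteins, glycogen cells and parietal giant cells lay higher, and genes of the inner syncytial layer, of sinusoidal giant cells and of smooth muscle lower, none with an estimated correlation. The edgeR test called 2328 of 15055 genes (1221 higher, 1107 lower; 282 and 290 at least 2-fold), with a median size of 0.6 and 4308 genes at an unadjusted p under 0.05. Cyp46a1 rose from 1.133 ± 0.261 to 11.24 ± 1.29 CPM (3.32 ± 0.3, adjusted p = 4.6e-05) and Sult1e1 from 5.516 ± 0.811 to 34.59 ± 2.87 (2.65 ± 0.14, adjusted p = 7.4e-07). Aldh1a3, for a retinoic acid synthesis enzyme, rose from 6.274 ± 3.34 to 38.41 ± 8.89 (2.63 ± 0.42, adjusted p = 0.012). Marco and Cd5l, of macrophages, rose from 0.1443 ± 0.0755 to 2.173 ± 0.544 CPM (3.84 ± 0.56, adjusted p = 0.00079) and from 0.4872 ± 0.018 to 4.711 ± 0.573 CPM (3.26 ± 0.34, adjusted p = 8.4e-05). The semaphorin gene Sema5b, the dopamine receptor gene Drd4, Gsg1l, Chrna2, Pla2g4d, Tmod1 and the antisense gene Rap1gapos rose by 2.62 to 3.13. Corin, for the protease that activates atrial natriuretic peptide, fell from 79.6 ± 5.18 to 11.1 ± 0.747 CPM (-2.84 ± 0.1, adjusted p = 3.2e-08). The ligand gene Wnt9b fell from 13.94 ± 3.71 to 0.9688 ± 0.105 (-3.84 ± 0.3, adjusted p = 4.1e-05) and the troponin gene Tnnc1 from 30.46 ± 5.8 to 4.148 ± 1.49 (-2.88 ± 0.22, adjusted p = 4.4e-05). Cel, Abo, Sbk3, Ripply1, Tmem45b, Ccdc42, Tmem145 and Etd fell, with changes of -4.32, -3.73, -3.31, -2.9, -2.78, -2.77, -2.65 and -2.62. The count was 1518 without DKO replicate 1, 1994 without WT replicate 1 and 1723 without DKO replicate 2, and 1443 without WT replicate 2. The genes named so far in this comparison were called each time. With indices chosen after the data were seen it was 1246 (Y-linked), 61 (natural killer) and 32 (yolk sac).

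In DKO at E18.5, 10 of 36 lists were called (7 higher, 3 lower), 0 with an estimated correlation (2 at an unadjusted p under 0.05). Cholesterol synthesis genes lay higher (median 0.4, adjusted p = 2.68e-06, adjusted p = 0.421 with an estimated correlation; 9 of 19 called, 12 adjusted over the list alone). Cyp51 rose from 18.96 ± 0.697 to 32.03 ± 0.791 CPM (0.76 ± 0.1, adjusted p = 0.00049) and the receptor gene Ldlr from 119 ± 6.41 to 180.6 ± 8.09 (0.6 ± 0.09, adjusted p = 0.0011). Steroid hormone synthesis lay higher (median 0.54, adjusted p = 0.00275, adjusted p = 0.421 with an estimated correlation; 4 of 11 called, 5 adjusted over the list alone). Cyp17a1 rose to 212.6 ± 7.32 CPM (1.29 ± 0.1, adjusted p = 1.4e-05) and Star from 70.03 ± 8.74 to 116.5 ± 2.2 (0.74 ± 0.1, adjusted p = 0.00038). Cyp11a1 rose from 72.68 ± 2.72 to 117.4 ± 5.91 (0.69 ± 0.09, adjusted p = 4e-04). Ribosomal protein genes lay higher (median 0.39, adjusted p = 5.99e-10, adjusted p = 0.688 with an estimated correlation; 18 of 30 called, 23 adjusted over the list alone). Rpl23 rose from 344.9 ± 22.9 to 492.6 ± 33.9 CPM (0.51 ± 0.1, adjusted p = 0.0043), beside Rpl7 and Rps8. Glycogen cell genes lay higher (median 0.29, adjusted p = 0.00576, adjusted p = 0.421 with an estimated correlation; 6 higher and 1 lower, list alone 7 and 2). Plac8 rose from 72.9 ± 11.6 to 304.8 ± 5.2 CPM (2.06 ± 0.12, adjusted p = 1.4e-06) and Pcdh12 from 63.37 ± 0.159 to 113.9 ± 6.4 (0.85 ± 0.08, adjusted p = 6.5e-05). Gjb3 fell from 136.2 ± 10.1 to 86.6 ± 12.3 (-0.65 ± 0.11, adjusted p = 0.002). Parietal giant cell markers lay higher (median 1.25, adjusted p = 1.53e-06, adjusted p = 0.421 with an estimated correlation; 6 of 7 called, 6 adjusted over the list alone). Prl2c5 reached 333.9 ± 11.8 CPM (1.2 ± 0.11, adjusted p = 3.1e-05) and Serpinb9d 22.23 ± 2.35 (1.38 ± 0.13, adjusted p = 4.2e-05), beside Prl2c3 and Serpinb9e. Natural killer cell markers, of maternal decidua, were higher beside them (median 1.81, adjusted p = 0.000174, adjusted p = 0.574 with an estimated correlation; 5 of 8 called, 7 adjusted over the list alone). Gzmg rose from 2.592 ± 0.255 to 10.78 ± 2.65 CPM (2.06 ± 0.28, adjusted p = 0.00077). Yolk sac markers were higher too (median 0.25, adjusted p = 0.0263, 1 called), which ended without DKO replicate 1 or WT replicate 1 (to 0.15). The other list calls held whichever library was left out.

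Lower in DKO at E18.5 were the cathepsin and sinusoidal giant cell genes (median -0.59, adjusted p = 0.00164, adjusted p = 0.589 with an estimated correlation; 4 of 8 called, 5 adjusted over the list alone). Ctsq fell from 23490 ± 462 to 7604 ± 926 CPM (-1.63 ± 0.16, adjusted p = 5.9e-05) and Lepr from 3841 ± 191 to 1292 ± 110 (-1.57 ± 0.13, adjusted p = 1.8e-05). Cts6 fell from 6236 ± 223 to 3773 ± 160 (-0.73 ± 0.13, adjusted p = 0.0027). Syncytiotrophoblast layer II lay lower (median -0.73, adjusted p = 0.0198, adjusted p = 0.479 with an estimated correlation; 5 lower and 1 higher of 9, the same adjusted over the list alone). The fusogen gene Synb fell from 19.3 ± 1.72 to 5.981 ± 1.99 CPM (-1.69 ± 0.18, adjusted p = 0.00017). So did Gcm1 (-1.56 ± 0.21, adjusted p = 0.00041). Smooth muscle genes lay lower (median -0.58, adjusted p = 3.23e-05, adjusted p = 0.574 with an estimated correlation; 4 of 11 called, 6 adjusted over the list alone). Lmod1 fell (-1.31 ± 0.15, adjusted p = 0.00021), as did Mylk, Myh11 and Cnn1, whose calls ended without DKO replicate 1 or WT replicate 2. Trophoblast progenitor markers were not called (median 0.08, adjusted p = 0.418, adjusted p = 0.78 with an estimated correlation; 4 higher and 1 lower, list alone 4 and 2). Among them Esrrb rose from 4.514 ± 0.214 to 19.38 ± 0.227 CPM (2.1 ± 0.13, adjusted p = 2e-06), Cdx2 by 1.43 ± 0.21 (adjusted p = 0.00071) and Eomes by 2.24. Bmp4 fell by 1.29.

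Of the 37 lists, 6 were not called in any comparison without a block (adjusted p = 0.0628 or more): the RNA-binding splicing regulators, heat shock genes, p53 targets, decidual stroma markers, genes flanking Mbnl2 and primitive erythroid globins (adjusted p = 0.0459 at E11.5 with the litter block).

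**Figure D2:**
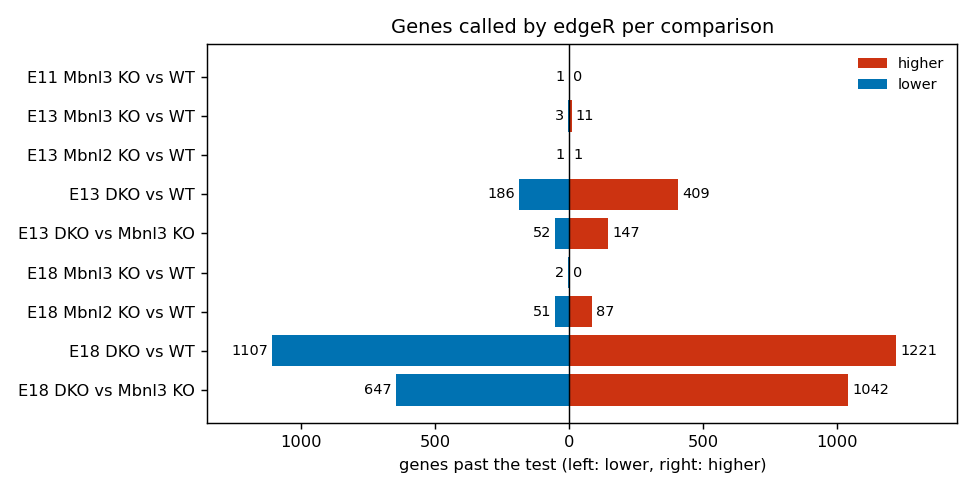
Number of genes called lower (left, blue) and higher (right, red) at an adjusted p below 0.05 in the 9 comparisons of 2 groups. DKO at E18.5 has 1107 lower and 1221 higher, the libraries labelled Mbnl2 KO at E18.5 have 51 and 87, and Mbnl3 KO has 14 calls or fewer at each stage.

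**Figure D3:**
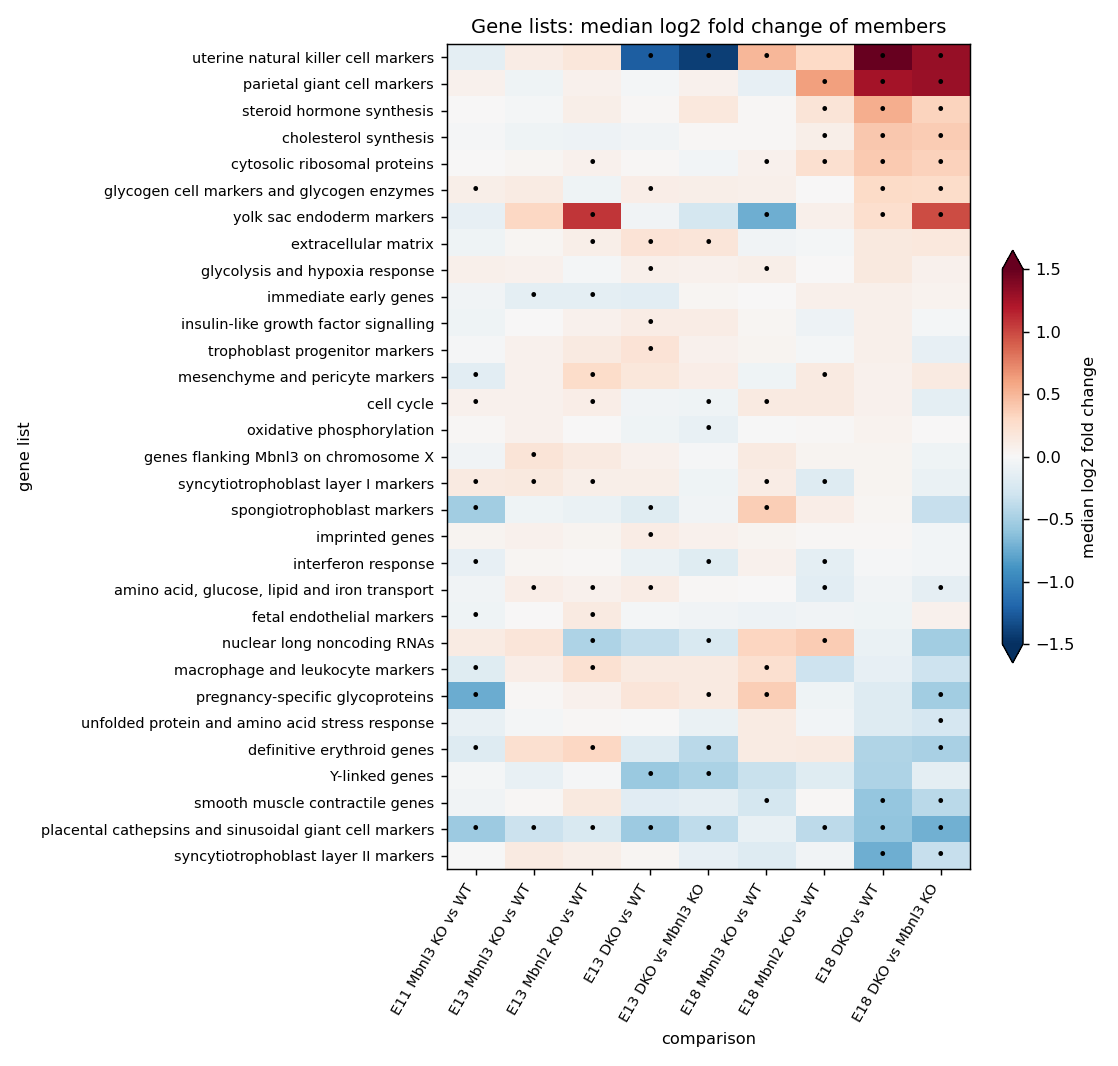
Median log2 change of the 31 gene lists called at least once (vertical) in the 9 comparisons (horizontal), with colour limited to 1.5 on either side and a dot for an adjusted p below 0.05. The cathepsin and sinusoidal giant cell list is negative in every column with a dot, from -0.23 to -0.72, and parietal giant cell markers reach 1.25 in DKO at E18.5.

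Against Mbnl3 KO at E18.5, the DKO labyrinth was compared with the same question. Cholesterol and steroid synthesis, ribosomal protein and parietal giant cell lists lay higher. Sinusoidal and inner syncytial lists lay lower, here with the unfolded protein response, none with an estimated correlation. Calls by edgeR numbered 1689 (1042 higher, 647 lower), with 3752 at an unadjusted p under 0.05. Esrrb rose from 2.194 ± 0.13 to 19.38 ± 0.227 CPM (3.14 ± 0.14, adjusted p = 2.8e-07) and Cyp46a1 from 1.728 ± 0.885 (2.7 ± 0.28, adjusted p = 0.00013). Drd4, Tmod1 and Sema5b rose by 2.99, 2.77 and 2.74. Corin fell from 77.7 ± 5.8 CPM (-2.81 ± 0.1, adjusted p = 7.3e-08) and Wnt9b from 16.95 ± 3.22 (-4.12 ± 0.3, adjusted p = 2.9e-05). Cel, Abo and Sh3rf3 changed by -4.49, -3.53 and -2.82. Without Mbnl3 KO replicate 1, 675 genes were called, without Mbnl3 KO replicate 2 790, without DKO replicate 1 1026 and without DKO replicate 2 1191. The genes named so far in this comparison were called each time. With indices chosen after the data were seen, the Y-linked one left 1480 calls, the natural killer one 185 and the yolk sac one 0 (558 at an unadjusted p under 0.05).

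In this comparison 14 of 36 lists were called (7 higher, 7 lower), 0 with an estimated correlation (4 at an unadjusted p under 0.05). Parietal giant cell markers had 7 of 7 members called higher (median 1.29, adjusted p = 5.22e-09, adjusted p = 0.308 with an estimated correlation). Prl2c5 rose from 128.7 ± 8.58 CPM (1.38 ± 0.11, adjusted p = 1.4e-05) and Prl3d3 from 5.381 ± 2.32 to 21.42 ± 0.0153 CPM (1.99 ± 0.26, adjusted p = 0.0015). Cholesterol synthesis lay higher (median 0.38, adjusted p = 4.95e-07, adjusted p = 0.368 with an estimated correlation; 9 called, 11 adjusted over the list alone). Ldlr (0.74 ± 0.09, adjusted p = 0.00038) and Insig1 (0.94 ± 0.14, adjusted p = 0.00094) rose. Ribosomal proteins (median 0.34, adjusted p = 8.04e-09; 8 called, 25 adjusted over the list alone), steroid synthesis (0.33, adjusted p = 0.00292) and glycogen cells (0.27, adjusted p = 0.0102) lay higher. Yolk sac markers (median 0.98, adjusted p = 1.29e-10, adjusted p = 0.0809 with an estimated correlation; 10 of 13 called, 12 adjusted over the list alone) were higher. Afp rose from 354.7 ± 84.3 to 979.3 ± 163 CPM (1.47 ± 0.16, adjusted p = 0.00027). Natural killer markers were higher too (median 1.31, adjusted p = 0.00078; 5 called, 6 adjusted over the list alone). Lower (adjusted p = 0.000754 to 0.0322) were the cathepsin list (median -0.72), syncytiotrophoblast layer II (-0.34), smooth muscle (-0.4), pregnancy-specific glycoproteins (-0.52), definitive erythroid genes (-0.49), transport (-0.13) and the unfolded protein and amino acid stress response (-0.25, adjusted p = 0.0139; 5 lower and 1 higher, list alone 6 and 1). With an estimated correlation the adjusted p of these 14 lists was 0.0809 to 0.874. The calls for transport and erythroid genes ended without DKO replicate 1 or Mbnl3 KO replicate 2, for smooth muscle without DKO replicate 1, for the glycoproteins without DKO replicate 2 or Mbnl3 KO replicate 2 and for the unfolded protein response without Mbnl3 KO replicate 2 (adjusted p to 0.35).

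**Figure D4:**
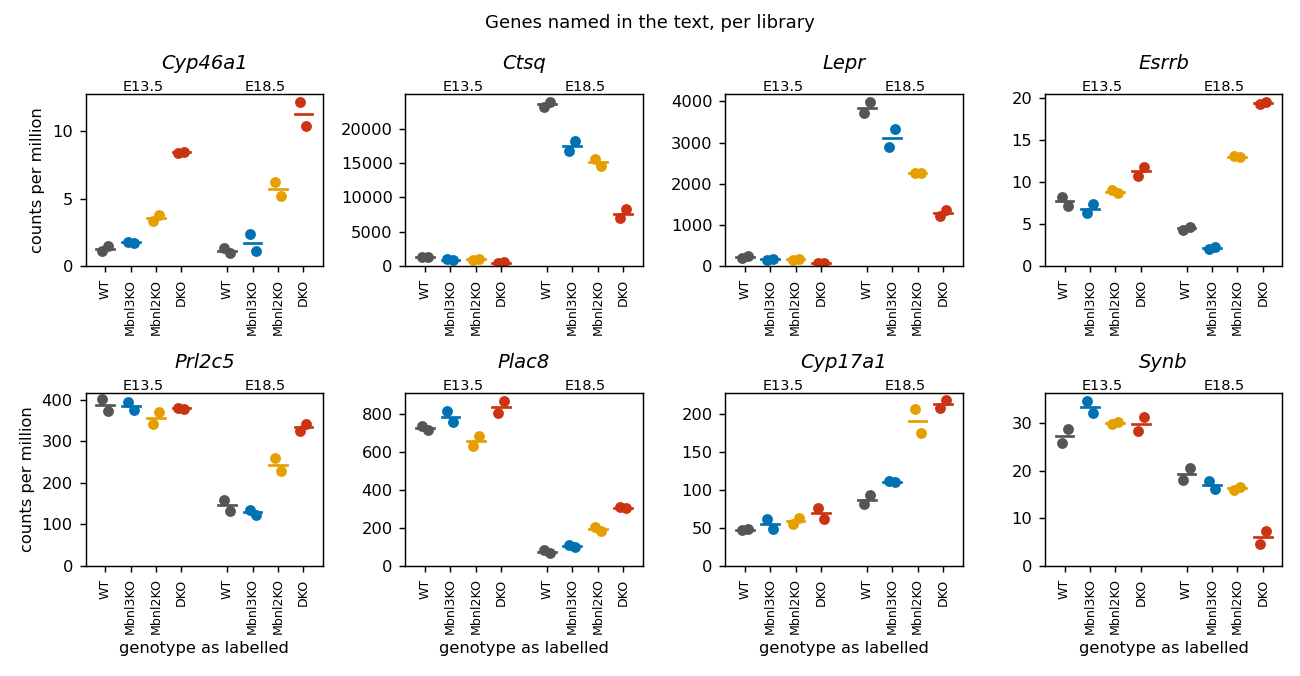
CPM of 8 genes in each library (dots) at E13.5 and E18.5 with group means (bars), by genotype as labelled. Cyp46a1 reaches 8.417 CPM in DKO at E13.5 and 11.24 CPM at E18.5 against 1.307 and 1.133 CPM in WT, and Ctsq falls to 547.1 and 7604 CPM against 1324 and 23490 CPM.

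Calls shared between genotypes were counted with their direction. Comparisons at 1 stage use the same WT libraries. At E18.5, 134 of the 138 genes called in the libraries labelled Mbnl2 KO were called the same way in DKO, 87 higher and 47 lower, and 0 the opposite way. Independent comparisons would share 7.06 and 3.75. Simulations without effects shared 0 to 0.15 genes per direction in every pair of this paragraph; with almost no calls, they cannot size what the controls add to these overlaps. The overlap was 179 without WT replicate 1, 42 without WT replicate 2 and 244 at an adjusted p below 0.1. Mbnl3 KO and DKO shared 12 genes at E13.5 (11 higher, and Mbnl3 itself lower; 0.289 and 0.0359 by chance), 3 without WT replicate 1 and 4 without WT replicate 2. At E18.5 they shared 2 (Mbnl3 itself and Slc39a2, both lower; 0.147 by chance), 27 without WT replicate 1 and 1 without WT replicate 2. The libraries labelled Mbnl2 KO and DKO shared 2 genes at E13.5 (1 higher, 1 lower; 0.0263 and 0.012 by chance), and 0 when either WT library was left out. Mbnl3 KO and the libraries labelled Mbnl2 KO shared 0 at E13.5 and 0 at E18.5, where leaving out WT replicate 1 gave 10. With 2 controls per stage, the controls could not be divided between comparisons, so part of each shared count is open to noise in the WT libraries.

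Whether the effect of a genotype differed between the E13.5 placenta and the E18.5 labyrinth was tested on the difference itself. For Mbnl3 KO 1 of 16007 genes differed, Sh2d4a, with 716 at an unadjusted p under 0.05 against 800 expected by chance. DESeq2 called 3, limma 0 (624 at an unadjusted p under 0.05) and edgeR without the filter 101. The Sh2d4a change was 0.66 ± 0.13 at E13.5 and -0.53 ± 0.11 at E18.5 (difference -1.18 ± 0.16, adjusted p = 0.027). This count was 0 without E13.5 Mbnl3 KO replicate 2, either E13.5 WT library, either E18.5 Mbnl3 KO library or E18.5 WT replicate 2. It was 3 without E18.5 WT replicate 1, and without E13.5 Mbnl3 KO replicate 1 the 1 gene called was another one. For DKO 929 genes differed (448 with a more positive effect at E18.5, 481 with a more negative one), and 2884 had an unadjusted p under 0.05. Without 1 library the count ran from 498 (E13.5 WT replicate 1) to 1027 (E18.5 WT replicate 1).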

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

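The tests of the Mbnl2 counts, of the giant cell and natural killer markers and of the Y-linked genes were chosen only after the results had been seen; the stage differences had been planned.

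The effect of a genotype differed between the E13.5 placenta and the E18.5 labyrinth by a test of the difference itself. For Mbnl3 KO this held for 1 gene, Sh2d4a, whose log2 change at E18.5 minus that at E13.5 was -1.18 (SE 0.16, adjusted p = 0.027). For DKO it held for 929 genes. Of these, 715 were called at E18.5 alone, 53 at E13.5 alone, 57 at both stages the same way, 92 at neither, and 12 in opposite directions, 9 of them higher at E13.5 and lower at E18.5. Named among the 12, after their values were seen, are Endou, a placental endoribonuclease gene (difference -2.24, SE 0.4), the glycine decarboxylase gene Gldc (-2.04, SE 0.24), the noncoding RNA gene Zfas1 (1.2, SE 0.21), the vesicle GTPase gene Rab3b (-1.2, SE 0.2), the tissue factor gene F3 (-1.2, SE 0.1) and the amino acid transporter gene Slc7a8 (-0.99, SE 0.16). Gldc changed by 0.64 and -1.4, F3 by 0.47 and -0.72, and Zfas1 by -0.56 and 0.65 at E13.5 and E18.5. Tissue and stage change together, so a difference in either stays open and untested.

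Mbnl2 counts were not lower in the libraries labelled Mbnl2 KO or DKO. Labels that carry no genotype would leave the 138 genes called at E18.5 in the libraries labelled Mbnl2 KO without a common direction between DKO and Mbnl3 KO, which share no library with them, but 99.3% (137) went the same way and 119 were called so, against 63.3% with the same sign over all genes. This argues against random labels at E18.5; a batch common to the libraries labelled Mbnl2 KO and DKO stays open, and at E13.5 the changes of all genes correlated by 0.06. Reads of Mbnl3 counted for Mbnl2 would make Mbnl2 fall where Mbnl3 is also lost, and its change in DKO at E18.5 was 0.3 (SE 0.12), which argues against this. A deletion that leaves most of the transcript counted is a candidate explanation that cannot be told apart from an intact gene here, since the change in the libraries labelled Mbnl2 KO at E18.5 was 0.16 and counts per gene hold no exons.

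Parietal giant cell and natural killer markers were higher in DKO at E18.5. Junctional zone tissue left on the labyrinth cannot be told apart from a change in the giant cells: its spongiotrophoblast markers had a median of 0.03 (SD 0.85 over 13 members) against 1.25 for the 7 parietal giant cell markers, but the glycogen cell list of that zone lay higher (median 0.29, 6 members called higher), and Tpbpa, at 5201 CPM in WT, would hide a small share. Decidua left on the labyrinth remains open for the natural killer markers and cannot be told apart from a change in these cells: the decidual stroma markers had a median of 0.19 (SD 0.89 over 10 members) against 1.81, and Prl8a2, made in decidua, changed by 2.37 (SE 1.04). A change in giant cell number or state is a biological hypothesis that was not tested.

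The Y-linked genes were lower in DKO at E13.5, where 595 genes were called. A lower share of male tissue in the DKO libraries would move no gene further than the sex-linked genes themselves, yet 37 called genes (6.2%) lay beyond those bounds by more than 2 SE, 11 below the lowest Y-linked gene (-1.06) and 26 above 0.76, which is 2 SE of Xist above 0. Xist itself changed by -0.49 (SE 0.38), not upward as less male tissue would give. This argues against sex as the cause for these 37. For the other 558 genes sex and genotype cannot be told apart: with the Y-linked index as a covariate the standard errors grew 3.7 times in the median, so the loss of calls decides nothing. A difference in sex between the libraries stays among the open explanations.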

How the results depend on the processing

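The index covariates were chosen after the data were seen; the other alternatives had been planned. Of 307 values of named genes and members, 306 kept direction and side of the threshold with RLE factors, 273 with DESeq2, 274 with the replicate block, 256 without the filter and, of 279, 224 with limma; none of these reversed. Leaving out 1 library kept 1027 of 1276, weakened 235 and reversed 5, all small changes at E13.5: Mbnl2 in Mbnl3 KO (0.02, range -0.13 to 0.02), in libraries labelled Mbnl2 KO (0.07 and 0.06, range -0.1 to 0.07) and in DKO (-0.03, range to 0.18), and Mbnl1 in DKO against Mbnl3 KO (0.01, range from -0.18). Of 94 list calls, 93 held with the replicate block and 1 with an estimated correlation. Leaving out 1 library kept 298 of 398 and reversed 3: the glycoproteins in DKO against Mbnl3 KO at E13.5 (-0.07 to 0.24) and ribosomal (-0.04 to 0.18) and spongiotrophoblast genes (0.07 to 0.71) in Mbnl3 KO at E18.5. Counts of calls by comparison were as follows, and the cause was not tested. For Mbnl3 KO at E11.5, DESeq2 gave 2 and every library left out 1. For Mbnl3 KO at E13.5 (14), no filter gave 339, DESeq2 85, limma 3, the Y-linked index 2, the natural killer index 50 and libraries left out 2 to 6. For the libraries labelled Mbnl2 KO at E13.5 (2), no filter gave 327, DESeq2 34, limma 1, the natural killer index 1 and edgeR with the replicate block, Y-linked or yolk sac index 0 (1230, 1165 and 1194 at an unadjusted p under 0.05), as did each library left out (722 to 1208). For DKO at E13.5 (595), no filter gave 1449, limma 209, the Y-linked index 1, the natural killer index 259 and libraries left out 103 to 519. Against Mbnl3 KO (199), it was 862, DESeq2 488, limma 32, the replicate block 84, the Y-linked index 0 (530 at an unadjusted p under 0.05), the natural killer index 15 and libraries left out 16 to 193. For Mbnl3 KO at E18.5 (2), no filter gave 131, DESeq2 54, limma 3, the replicate block 112, the Y-linked index 1, the yolk sac index 0 (425 at an unadjusted p under 0.05), the natural killer index 6 and libraries left out 1 to 36. For the libraries labelled Mbnl2 KO at E18.5 (138), no filter gave 446, DESeq2 237, limma 48, the replicate block 513, the Y-linked index 79, the yolk sac index 52 and libraries left out 32 to 188. For DKO at E18.5 (2328), the Y-linked index gave 1246, yolk sac 32, natural killer 61 and libraries left out 1443 to 1994. Against Mbnl3 KO (1689), the replicate block gave 2820, the yolk sac index 0 (558 at an unadjusted p under 0.05), natural killer 185 and libraries left out 675 to 1191. The stage difference of Mbnl3 KO (1) was 101 without the filter, 3 with DESeq2, 0 with limma (624 at an unadjusted p under 0.05) and 0 to 3 with libraries left out, that of DKO (929) 498 to 1027. With an estimated correlation, lists called fell to 0 in each comparison but Mbnl3 KO at E18.5 (1). Libraries left out gave 4 to 17 lists at E11.5, and at E13.5 4 to 15 (Mbnl3 KO), 11 to 17 (labelled Mbnl2 KO), 9 to 16 (DKO) and 13 to 15 (DKO against Mbnl3 KO), and at E18.5 7 to 14, 8 to 13, 11 to 16 and 12 to 14. Of the lists called with all libraries, these kept as few as 3 of 11 at E11.5, 2 of 5, 8 of 13, 6 of 11 and 7 of 10 at E13.5 and 4 of 10, 5 of 10, 9 of 10 and 10 of 14 at E18.5. At E11.5 the litter block added 4 lists and changed no other call. The index covariates changed standard errors 0.9 to 7.4 times in the median, and where they widened much, lost calls decide nothing. At a ratio of 1.4 or less, calls still fell to 79 (Y-linked, ratio 1) and 52 (yolk sac, 1.2) for the libraries labelled Mbnl2 KO at E18.5, and at E13.5 to 0 (Y-linked, 1.1, and yolk sac, 1.3) and 1 (natural killer, 1). So they did to 2 for Mbnl3 KO at E13.5 (Y-linked, 1.4), to 259 and 15 for DKO at E13.5 against WT and Mbnl3 KO (natural killer, 1.4), and at E18.5 to 1246 for DKO (1.3) and 1 for Mbnl3 KO (1.1) with the Y-linked index. Replicate numbers at E13.5 and E18.5 are not stated to mark litters; correlations of same-numbered libraries were -0.15 to 0.14 and 0.06 to 0.35, and at E18.5 replicate 1 lay above replicate 2 on the second principal component in all 4 genotypes (6.2 to 17.9 and -26.9 to 3.9), a hint from the data and not the design. The pseudocount was not varied, since counts exist. Overlaps at an adjusted p below 0.1 were 35 (Mbnl3 KO and DKO) at E13.5 and 14 and, with the libraries labelled Mbnl2 KO, 244 at E18.5. Leaving out a WT library gave 179 or 42 for the latter, 27 or 1 for Mbnl3 KO and DKO and 10 or 0 for both singles at E18.5, and 3 or 4 for Mbnl3 KO and DKO at E13.5. Depth limits genes near 1 CPM, where a group mean rests on few reads.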

Other observations

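The tests near Mbnl2 and Mbnl3 were chosen only after the results had been seen; those of the splits, of the sum of single effects and of the stage axis had been planned before.

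Corin and Wnt9b were among genes that fell in DKO at E18.5 by more than both single knockouts together would give. Corin departed from the sum of the single changes by -2 (SE 0.14, adjusted p = 9.7e-05), Wnt9b by -2.95 (SE 0.39, adjusted p = 0.023), the Wnt inhibitor gene Dkk1 by -1.97 (SE 0.3, adjusted p = 0.024) and the vasodilator gene Adm, adrenomedullin, by -1.13 (SE 0.15, adjusted p = 0.017). The cation channel gene Trpv2 departed upward by 1.14 (SE 0.13, adjusted p = 0.0088). Afp departed by 1.41 (SE 0.23, adjusted p = 0.04), which rests on its change of -1 in Mbnl3 KO against 0.47 in DKO, and Esrrb by 1.61 (SE 0.2, adjusted p = 0.01), in part from -1.04 in Mbnl3 KO. These genes were chosen for naming after their values were seen.

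A hypothesis set before the test was that loss of both genes does more than the sum of the losses of each, with more than 10 departing genes. At E18.5, 44 genes departed (30 higher, 14 lower; 142 with DESeq2, 5 with limma; 1573 at an unadjusted p under 0.05 against 753 expected by chance), in line with the hypothesis with edgeR for the genotypes as labelled. The 5 of limma lie within the bound of 10 set against it, and a departure such as that of Afp is no larger effect. At E13.5 edgeR gave 0 departing genes, with 1737 at an unadjusted p under 0.05 against 778 expected by chance, 160 with DESeq2 and 3 with limma. The bound of 10 genes or fewer set against the hypothesis was too weak for this excess of small p-values, so E13.5 is undecided. This contrast carries the noise of all 4 genotypes.

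Another hypothesis was a less advanced placenta in DKO. Across 15054 genes, which are not independent replicates, the DKO changes at E18.5 ran against the change of Mbnl3 KO from E13.5 to E18.5 (Spearman's rho -0.28, Pearson's r -0.32), as did 1774 of 2327 called genes (76.2%); the libraries labelled Mbnl2 KO gave a rho of -0.12. This is the direction a delay may give, but whole placenta was sampled at E13.5 and labyrinth at E18.5, so delay and tissue makeup cannot be told apart.

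At E11.5, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many calls as the real one, which gave 1; the highest of the others was 0, also among the 4 splits that part every litter. So few splits cannot reach a share under 0.05. The 1 call was Mbnl3 itself, so they say nothing of other genes.

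Sequence linked to the targeted allele could be carried along and change genes near Mbnl2. Within 3 Mb of it, 8 of 26 genes were called in DKO at E18.5 against 15.4% elsewhere (odds ratio 2.43, Fisher's exact test, two-sided, p = 0.05, adjusted p = 0.075), and 2 of 26, Tgds and Uggt2, in the libraries labelled Mbnl2 KO against 0.9% elsewhere (odds ratio 9.12, Fisher's exact p = 0.023, adjusted p = 0.07). Near Mbnl3, 7 of 33 were called in DKO (odds ratio 1.47, Fisher's exact p = 0.34, adjusted p = 0.34). Adjusted over these 3 tests, none passed, and a linked effect remains open.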
